A study of Arabidopsis thaliana with 6 samples.

How the data were processed

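RNA of the aerial tissue of 18-day-old Arabidopsis thaliana plants was sequenced after ribosomal RNA depletion from 10 µg of total RNA. There were 6 genotypes with 1 library each: wild type Col-0, ein5-1, ski2-3, ein5-1 ski2-3 (the double mutant), rdr6-11, and rdr6-11 ein5-1 ski2-3 (the triple mutant). Plants grew at 22 °C with 16 h of light and 8 h of dark, per the labels' protocols. EIN5 (also XRN4) is a cytoplasmic 5'-to-3' exonuclease, SKI2 is the helicase of the complex that feeds the cytoplasmic exosome, and RDR6 is an RNA-dependent RNA polymerase that makes double-stranded RNA for small interfering RNAs.

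The deposited table held read counts per gene for the 6 libraries, per the file headers and the values, which were whole numbers with a different total in each library. The submitters' processing notes name BWA and the TAIR9 build, with no version of BWA. How reads were assigned to genes, and whether strand was used, was not given in the sources used here. The authors also deposited RPKM values, log2 ratios of RPKM for 9 pairs of libraries, p-values and false discovery rates. The test behind the deposited p-values was not given in the sources used here, and they and the false discovery rates, deposited scores without a stated method, were not used. Cells without a value were taken as 0 reads. This was checked on the authors' ratios: in all 14709 ratios with 1 such cell, the missing RPKM came out as 0.001 within 1e-05, and the 241037 ratios with both values present differed from the log2 ratio of the RPKM values by no more than 0.001.

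The table held 33602 genes, of which 33323 were nuclear, 133 chloroplast and 146 mitochondrial. The TAIR10.1 gene table was used for names, gene classes and neighbouring genes only, and 32835 identifiers matched it. The 767 others kept the identifiers of the deposited table. No coordinates were taken from it, since the build differs. The count and RPKM columns each belonged to 1 of the 6 libraries, and the other columns of values to pairs of them.

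Ratios were computed from the counts of nuclear genes. Libraries were scaled by the trimmed mean of M-values on nuclear genes, written in numpy with trims of 0.3 on log ratios and 0.05 on mean expression. A pseudocount of 0.5 was added to each count, scaled to the library. Each log2 ratio between 2 libraries has an exact 95% interval from the conditional binomial distribution of its 2 counts (Clopper-Pearson). The 4 ribosomal RNA and 623 transfer RNA genes were left out after scaling. A gene was measured in a comparison if the library with more reads had at least 100 reads, and it was called different if its ratio was at least 2-fold. This is a rule of size and not a test. With 1 library per genotype, single genotypes could not be tested against each other, and no model of allele effects across the genotypes was fitted. No p-value or standard error is therefore given. Intervals and floors cover counting error only, since the reads were amplified by PCR and have no molecular identifiers. Where a gene had 0 reads in 1 of the libraries, its ratio is given as a bound against a floor of 3 reads per library.

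The comparisons were each mutant against Col-0, the double mutant against the triple mutant, and the triple mutant against rdr6-11. Non-additivity was the log2 ratio of the double mutant against Col-0 minus the sum of the ratios of ein5-1 and of ski2-3. RDR6-dependence was described by taking the genes at least 2-fold different between the double mutant and Col-0 and computing the same loss of EIN5 and SKI2 in the rdr6-11 background, as the triple mutant against rdr6-11. The share of the log2 difference kept is the second ratio over the first, in percent. Correlations are across genes, which are not independent replicates. For pairs of comparisons that share the Col-0 library, 100 simulated sets of unchanged libraries gave the overlap and correlation that arise at set noise. This noise, an SD of 0.132 in log2 per library besides counting error, came from the triple mutant against rdr6-11. Only genes with at least 1000 reads in both were used for it.

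The comparisons, the read minimum, the size rule, the rule for named genes and the members of the gene lists were fixed before the data were examined. The rule named the 10 highest and 10 lowest genes of each comparison, the targeted genes, the members of the lists, and the 10 genes highest in the double mutant against both Col-0 and the triple mutant. The lists were the targeted genes, known siRNA source genes, the SMXL family, RNA silencing factors, RNA decay factors, miRNA target genes, tasiRNA precursors and target genes, anthocyanin and flavonoid synthesis, ethylene response, salicylic acid and defence, jasmonate response, nitrate assimilation, photosynthesis, responses to abscisic acid, cold and drought, heat shock, phosphate starvation, senescence, glucosinolate synthesis, the circadian clock, flowering and floral organs, and root markers. List members were dropped if the gene table held a name of the same letters with another number, and not the list's own name. This removed HTT1, HTT2 and HTT3 from the tasiRNA targets and F3PRIMEH (AT5G07990) from the anthocyanin list. The rule compares strings only, so a dropped gene need not be miscoded. Each list's median log2 ratio was set against those of 10000 random lists of the same size, matched on mean expression in 20 bins. A percentile is given as a description of these libraries.

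The computation was tested on simulated data for the comparison of the double mutant with Col-0. Counts of 33323 genes were drawn from the means and depths of the real libraries, with 200 genes altered, and 14964 genes passed the read minimum. At least 2-fold was found for 46% of 100 genes altered 2-fold, for 100% of 50 genes altered 4-fold and of 50 altered 8-fold, and for 0% of 14764 unaltered genes. The interval covered the true value for 95.3% of the unaltered genes. Of 500 lists of unaltered genes, 5.4% lay outside the 2.5 to 97.5 percentile range. Counts were Poisson draws, with no variation between libraries beyond counting error. The simulation thus checks the computation and does not give the rate of false calls in real libraries.

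Alternatives fixed beforehand were scaling by total nuclear counts, by median-of-ratios size factors (own code) and by total counts including organelle genes, a pseudocount of 5, read minimums of 20 and none, the authors' own log2 ratios, a 4-fold rule, and a rule that the whole counting interval lie beyond 2-fold. Added after the data were seen were protein-coding genes only, total nuclear counts without ribosomal RNA genes, halved counts of the libraries with rdr6-11, and leaving out genes at least 2-fold different between rdr6-11 and Col-0. Organelle genes were left out of the comparisons because their share of the reads depends on RNA depletion. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.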

Results

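The data were read counts per gene from 6 libraries of aerial tissue, 1 per genotype. The libraries held 20205663 reads (Col-0), 22789530 (ein5-1), 24366687 (ski2-3), 33100379 (double mutant), 28074011 (rdr6-11) and 30565543 (triple mutant). Between 10942840 reads in Col-0 and 16593256 in the double mutant fell on nuclear genes. Chloroplast genes took from 44.4% of the reads in Col-0 (95% Clopper-Pearson interval 44.39 to 44.43) to 53.9% in ski2-3 (53.93 to 53.97). Ribosomal RNA genes took 19.2% of the nuclear reads in Col-0 (19.15 to 19.20), and between 0.335% (0.331 to 0.338, ski2-3) and 2.71% (2.70 to 2.72, double mutant) in the mutants. A count of 3 reads, the floor used for genes without reads, corresponded to 0.181 to 0.274 reads per 1e+06 nuclear reads. There were no replicates, so no difference below has a replicate check, and each compares libraries, not populations of plants.

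The libraries fell into different counting patterns. Of the genes with 1 to 20 reads, 81.9% (81.1 to 82.6) in rdr6-11 and 81.4% (80.6 to 82.3) in the triple mutant had an even count, against 38.5% to 41.6% in the other 4 libraries. Counting intervals are too narrow in those 2 libraries if each fragment was counted by both of its reads.

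The 3 targeted genes were lower in the libraries that carry their mutant alleles, though transcripts of each were still detected. EIN5 (AT1G54490) had a log2 ratio to Col-0 of -1.05 in ein5-1 (interval -1.25 to -0.86), -0.54 in the double mutant (-0.69 to -0.39) and -1.26 in the triple mutant (-1.44 to -1.08), against 0.33 in ski2-3 and 0.00 in rdr6-11. SKI2 (AT3G46960) stood at -0.65 in ski2-3 (-0.92 to -0.38), -0.37 in the double mutant (-0.59 to -0.14) and -0.78 in the triple mutant (-1.03 to -0.53), against 0.05 in ein5-1 and -0.04 in rdr6-11. RDR6 (AT3G49500) stood at -1.77 in rdr6-11 (-2.03 to -1.52) and -1.53 in the triple mutant (-1.77 to -1.31), against -0.47 in ein5-1, -0.10 in ski2-3 and -0.17 in the double mutant. Read counts for Col-0, ein5-1, ski2-3, the double mutant, rdr6-11 and the triple mutant were 599, 370, 845, 832, 835 and 422 for EIN5, 279, 370, 199, 437, 377 and 274 for SKI2, and 433, 401, 453, 779, 176 and 252 for RDR6. Signs of 4 of these values depended on scaling. With total nuclear counts SKI2 stood at 0.05 in the double mutant and 0.17 in rdr6-11, and RDR6 at 0.06 in ski2-3. RDR6 in the double mutant stood at 0.25 with total nuclear counts, 0.13 with organelle reads in the total and 0.12 with the authors' ratios.

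Loss of EIN5 alone came with lower expression of jasmonate response genes. RRTF1, ERF13 and ORA47, transcription factors of the AP2/ERF family, were among the genes with the lowest ratios, at -3.70 (-4.39 to -3.12), -3.64 (-4.39 to -3.02) and -3.34 (-3.87 to -2.87). All 10 measured jasmonate response genes had negative ratios, and 4 were at least 2-fold lower, among them JAZ7 (-1.72), a repressor of jasmonate signalling, and the biosynthetic genes OPR3 (-1.39) and AOC1 (-1.39). Among the highest genes were PYL6 (2.98, 2.28 to 3.86), an abscisic acid receptor, HB23 (2.25), a homeobox gene, EXPA1 (2.23), an expansin that loosens cell walls, and PR1 (1.93), a marker of salicylic acid responses. The comparison asked what the exonuclease does by itself. Of 12987 genes measured, 187 were at least 2-fold higher and 265 lower.

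Among the fixed lists, the jasmonate median of -0.94 lay below all 10000 random lists of the same size matched on mean expression, as a description of these libraries. Against the same Col-0 library it was also low in rdr6-11, which has EIN5 (-0.77), in the double mutant (-0.84) and in the triple mutant (-1.17). In ski2-3 it was 0.55. A low jasmonate list was thus not particular to loss of EIN5. The lists of abscisic acid, cold and drought (-0.32, percentile 0.16) and of anthocyanin synthesis (-0.42, percentile 0.54) were low, and photosynthesis was high (0.21, percentile 98.62). Of the 24 measured RNA decay factors, CAF1A (-1.63) and CAF1B (-1.16), subunits of the deadenylase complex, were at least 2-fold lower, and the list median was 0.01. The ethylene response list, of interest because ein5 was found as an ethylene-insensitive mutant, had a median of -0.01 with 3 of 14 genes lower: PDF1.2 (-1.70), HEL (-1.14) and HCHIB (-1.02). Small nucleolar RNA genes were lower in 5 of 6 cases in ein5-1, in ski2-3 and in the double mutant, with medians of -2.45, -2.20 and -2.88, while in rdr6-11 2 of 7 were higher and 1 lower (median 0.08). In the triple mutant, which carries the ein5-1 and ski2-3 alleles as well, 2 of 7 were higher and 3 lower (median -0.67). The share of higher genes among those different was 41.4%, and it was 74.3% with scaling by total nuclear counts, 65.4% with organelle reads in the total and 63.2% with the authors' ratios.

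Loss of SKI2 alone came with higher expression of defence genes. PR1 was at 3.07 (2.67 to 3.51), and the plant defensin genes PDF1.3 (3.20) and PDF1.2 (2.68) were among the highest, as were HAK5 (2.91, 2.22 to 3.77), a potassium transporter, and BAM5 (2.62), a beta-amylase. The defensin genes PDF1.2, PDF1.2b, PDF1.2c and PDF1.3 are near-identical copies that can share reads, so which copy was read is uncertain. PR1 was also higher than in the same Col-0 library in ein5-1, in the double mutant (1.53) and in the triple mutant. Of 12520 genes measured, 304 were at least 2-fold higher and 146 lower. The lowest were AT2G35208 (-7.54), without a class in the gene table, and AT1G29418 (-5.34) and AT2G01021 (-5.05), classed there as protein-coding. Reads of ribosomal RNA genes were lower in ski2-3 too: AT2G01021 had 12718 reads in Col-0 and 429 in ski2-3, and they had 2098477 and 36719. Whether they go together in the other libraries was not examined.

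Salicylic acid and defence genes were higher in 5 of 15 cases with a median of 0.74, above all 10000 random lists, among them PR2 (1.94), PR5 (1.82) and CYP71A13 (1.85), an enzyme of camalexin synthesis. Against the same Col-0 library this list was also high in rdr6-11, which has SKI2 (0.44, percentile 99.95), and in the triple mutant (0.90). It was 0.14 in ein5-1 and 0.31 in the double mutant. A high defence list was thus not particular to loss of SKI2. Anthocyanin genes had positive ratios in all 10 measured members (median 0.83, above all 10000 random lists), with UF3GT (1.33) and AT5MAT (1.17) at least 2-fold higher. The jasmonate list (0.55, percentile 99.92) and senescence (0.44, percentile 99.61) were also high, and VSP1 (1.23), SAG13 (1.38) and WRKY6 (1.03) passed 2-fold. The miRNA target list had a median of 0.32 (percentile 99.94), with 0 of 33 members at least 2-fold higher. The ethylene response list had 3 of 14 members higher (PDF1.2, HCHIB at 1.72 and HEL at 1.47) and a median of 0.16. Higher genes made up 67.6% of those different, but 85.6% with total nuclear counts, 49.5% with organelle reads in the total, 48.9% with the authors' ratios and 43.3% with total nuclear counts without ribosomal RNA genes.

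Loss of both EIN5 and SKI2 came with a different profile: genes of the heat shock response, of anthocyanin synthesis and of abscisic acid and cold responses were higher, while the plant defensin genes PDF1.2, PDF1.2b, PDF1.2c and PDF1.3 were lower. Transcripts of small heat shock proteins, chaperones with few or no reads in Col-0, were abundant. HSP17.6A had 1218 reads, at least 201-fold higher than Col-0, and HSP17.6II had 1215, at least 200.5-fold higher, though these related copies can share reads. HSP22 was at least 122-fold higher and HSP21, a chloroplast chaperone, at least 86.3-fold. NUDT24, a Nudix hydrolase, was at least 278-fold higher, and HSP17.4 stood at 8.14 (6.25 to 14.03). The comparison asked what is lost when both cytoplasmic decay routes are impaired.

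In this comparison 15068 genes were measured, of which 1289 were at least 2-fold higher and 1061 lower, 15.6% in all against 3.48% for ein5-1 and 3.59% for ski2-3. Heat shock genes were higher in 14 of 15 measured cases (median 3.63, or 3.66 with genes without reads at the floor), including HSP70 (3.05), HSP90.1 (2.68) and HSP101 (2.50). Anthocyanin and flavonoid genes were higher in 13 of 14 cases (median 2.75, or 2.76 at the floor), among them the MYB activators PAP2 (4.55) and PAP1 (18 reads in Col-0 and 688 in the double mutant), UF3GT (4.11), TT19 (3.60) and CHS (2.67), the first enzyme of the pathway. Abscisic acid, cold and drought genes were higher in 8 of 14 cases (median 1.15), with KIN1 (3.44), COR15A (3.12) and NCED3 (1.54), an enzyme of abscisic acid synthesis. These 3 medians lay above all 10000 random lists. Phosphate starvation genes were higher in 3 of 5 cases (1.45, or 1.47 at the floor, percentile 99.81), led by PAP17 (2.56), an acid phosphatase. In ein5-1 against Col-0 only 3 heat shock, 6 anthocyanin, 10 abscisic acid and 1 phosphate starvation gene were measured. The others here passed the read minimum only through the double mutant, which by itself favours a higher ratio.

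Some miRNA target genes and silencing factors were also higher. Of 37 measured miRNA target genes, 9 were at least 2-fold higher and 0 lower, with a median of 0.55, above all 10000 random lists: NFYA5 (3.14), ARF10 (1.70), AGO2 (1.57) and NFYA2 (1.49) led the list. The miRNA target list was high in ski2-3 alone as well (median 0.32, percentile 99.94). Of 19 RNA silencing factors, 5 were higher (median 0.39, percentile 97.64), with AGO2, AGO7 (1.26), AGO3 (1.21), RDR1 (1.04) and SGS3 (1.00), which acts with RDR6. AGO2 counts in both lists. RDR1 and SGS3 lay close to the 2-fold line, and with median-of-ratios size factors both fall below it. Among tasiRNA target genes, 3 of 11 were higher (median 0.47, or 0.48 at the floor, percentile 87.29), of which PAP1 and PAP2 belong to the anthocyanin list, and the pentatricopeptide gene AT1G63400 stood at 1.05. The tasiRNA precursors had a median of -0.09, and the 25 measured RNA decay factors 0.12 with only LSM1A lower (-1.09).

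Nitrogen, light and hormone genes differed in smaller ways. Of 13 nitrate assimilation genes, 4 were lower, namely NIR1 (-1.24), NIA1 (-1.22), GLN2 (-1.16) and UPM1 (-1.06), and 2 were higher, GLN1.1 (1.36) and ASN1 (1.11). The known siRNA source genes had a median of -0.49 with 1 of 4 lower: NIA1, NIA2 (-0.63), SMXL4 (-0.36) and SMXL5 (0.06). This list was chosen by the study's authors on plants of these genotypes, so it is not independent evidence. In the SMXL family 1 of 8 was at least 2-fold higher, SMAX1 (1.07), a regulator of karrikin signalling, with a median of 0.40. Photosynthesis genes had a median of -0.71 (percentile 6.04) with 2 of 25 lower, RBCS2B (-1.33) and RBCS3B (-1.11), subunits of Rubisco whose near-identical copies can share reads. Jasmonate genes had negative ratios in all 10 cases, 4 of them at least 2-fold (median -0.84, percentile 0.26), led by JAZ7 (-3.25). The salicylic acid list had 4 members higher and 2 lower of 16 (median 0.31), with PR2 (2.51) and CYP71A13 (-2.66) at the ends. Medians were 0.21 for ethylene response, 0.35 for senescence, -0.10 for glucosinolate synthesis, whose regulator MYB28 stood at 1.71, and -0.10 for the clock. Of the floral list 2 genes were measured, the repressor FLC (2.68) and the activator SOC1 (-1.11), and 0 root markers reached 100 reads.

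Among the genes with the lowest ratios were PDF1.3 (-5.85, -6.63 to -5.23), PDF1.2b (-5.37), ELI3-2 (-4.88), PDF1.2c (-4.85) and TPS04 (-4.79), which makes a volatile terpenoid precursor. Of the different genes 54.9% were higher, but 87.1% with total nuclear counts, 80.8% with organelle reads in the total, 80.2% with the authors' ratios and 68.8% with total nuclear counts without ribosomal RNA genes. With median-of-ratios size factors the majority turned, to 49.6% (1168 higher and 1189 lower). The median log2 ratio of the measured genes was 0.08 here, 0.49, 0.38, 0.37 and 0.22 with those 4 scalings, so values should be read relative to these shifts.

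**Figure D1:**
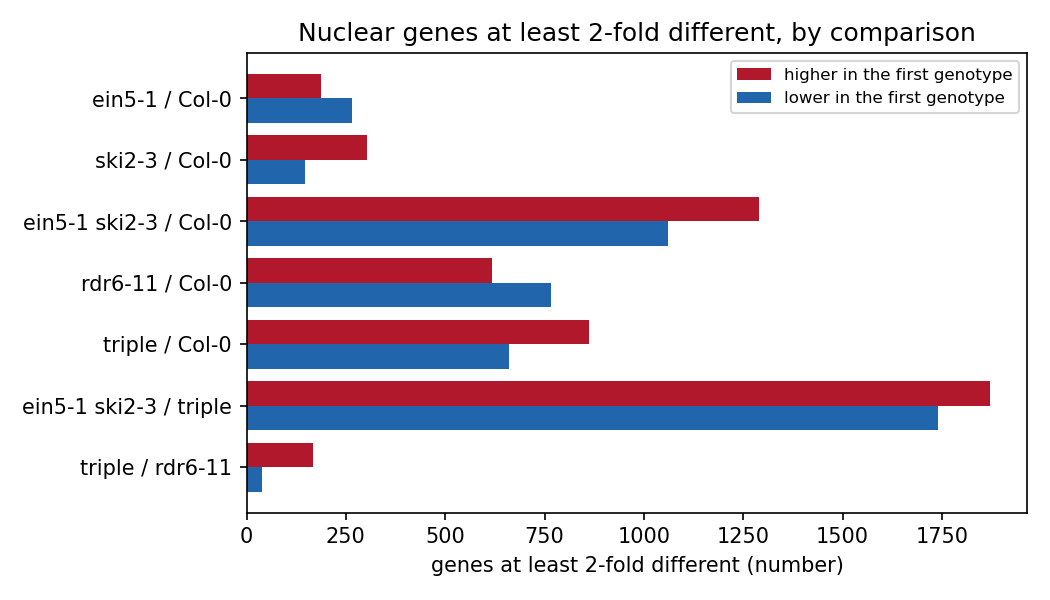
Number of nuclear genes at least 2-fold higher (red) or lower (blue) in the first genotype of each comparison, with 1 library per genotype. The bars are longest for the double mutant against the triple mutant (1872 and 1740) and shortest for the triple mutant against rdr6-11 (167 and 39).

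In these libraries the log2 ratios of the 2 single mutants did not add up to those of the double mutant. The double mutant departed from the sum of the single-mutant log2 ratios by at least 2-fold for 16.5% of 15193 genes, 1207 upward and 1294 downward. This share was near the 15.6% of genes different between the double mutant and Col-0. Each departure carries the variation of every library in it, and no value for unchanged libraries was computed. Heat shock genes departed upward in 14 of 15 cases (median 3.88), anthocyanin genes in 12 of 14 (2.62), abscisic acid genes in 10 of 14 (1.95) and phosphate starvation genes in 4 of 5 (1.86). Most of these heat shock genes passed the read minimum only through the double mutant, which by itself favours an upward departure. Silencing factors departed upward in 3 of 19 cases (0.45, percentile 99.76). Downward departures were found for HAK5 (-6.12), PDF1.3 (-6.10), PDF1.2 (-4.96) and ABCG40 (-4.60), a transporter of abscisic acid, and for 6 of 13 nitrate genes (median -0.97, percentile 0.71) and 10 of 25 photosynthesis genes (-0.75, percentile 16.77). Across 15193 genes the effect of losing EIN5 in Col-0 and in ski2-3 had a Pearson's r of 0.15 (Spearman's rho 0.12), and that of losing SKI2 in Col-0 and in ein5-1 an r of 0.08 (rho 0.09). Upward departures made up 48.3% of the total, and 69.6% with organelle reads in the total, 70.7% with the authors' ratios and 76.1% with total nuclear counts without ribosomal RNA genes.

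The rdr6-11 library differed from Col-0 in its clock genes, and tasiRNA precursors were higher. All 4 measured tasiRNA precursors were at least 2-fold higher, with TAS2 at 2.03 and TAS1A at 1.46 (median 1.75, percentile 99.97). ARF4 (1.54) and ARF3 (0.78), auxin response factors that TAS3 siRNAs target, were among 7 measured tasiRNA targets, of which 1 was at least 2-fold higher (median 0.78, percentile 99.9). The morning clock genes CCA1 (6.39, 5.29 to 8.15), RVE8 (5.42, 3.86 to 8.80), LHY (5.31, 3.96 to 7.82), PRR9 (5.28, 3.71 to 8.65) and PRR7 (2.56) were higher, while the evening genes ELF4 (-6.24, -9.62 to -4.68), LUX (-2.67), TOC1 (-2.53) and PRR5 (-2.29) were lower and GI, also an evening gene, stood at 0.42. TRX3 (AT5G42980), a cytosolic thioredoxin, had 4641 reads in Col-0 and 0 in rdr6-11, at least 2149-fold lower.

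Of 13300 genes measured, 617 were at least 2-fold higher in rdr6-11 than in Col-0 and 767 lower, with the morning genes' median at 5.31 and that of the evening genes at -2.53. Photosynthesis genes were higher in 16 of 25 cases (median 1.46, above all 10000 random lists), led by the light-harvesting genes LHCB2.3 (6.44) and LHCB2.1 (5.64), whose copies can share reads. Abscisic acid, cold and drought genes were lower in 7 of 11 cases (median -1.26, below all 10000), among them COR15B (-4.37) and HAI1 (-3.54), and heat shock genes had 1 of 4 lower, HSP90.1 (-1.27). The SMXL family was lower in 3 of 8 cases (median -0.97, percentile 0.01), with SMXL2 at -1.25. Jasmonate genes were lower in 4 of 10 cases and higher in 1 (median -0.77), with VSP1 at -4.17 and LOX2 at -3.31, and salicylic acid genes were higher in 4 of 15 and lower in 2 (median 0.44, percentile 99.95), with ICS1 at 2.11 and PAD3 at -4.96. Other genes at the ends were BBX16 (at least 85.4-fold higher), the blue-light receptor FKF1 (-6.92) and the cold-regulated gene COR27 (-7.13). Of those different, 44.6% were higher, but 64.3% with total nuclear counts.

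**Figure D2:**
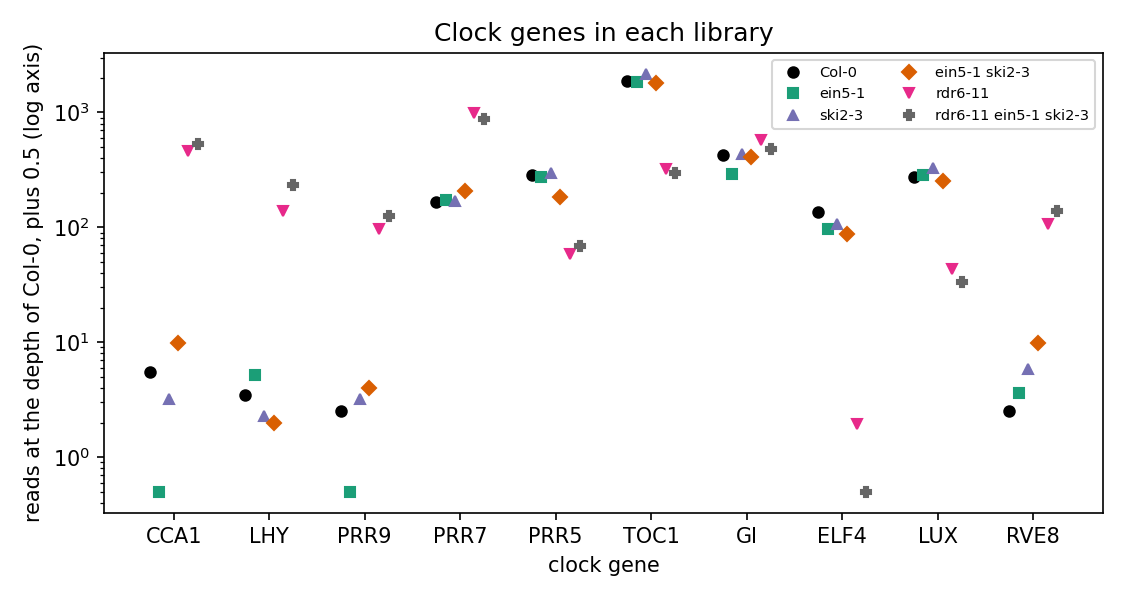
Reads of the 10 clock genes in each library, scaled to the depth of Col-0 with 0.5 added, on a log axis; each symbol is 1 library. CCA1, LHY, PRR9 and RVE8 were high in rdr6-11 and the triple mutant only, and ELF4, LUX and TOC1 were low there.

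The triple mutant differed from Col-0 in the same clock genes as rdr6-11. Against Col-0 the morning median was 5.78 and the evening median -2.64, with PRR9 at 5.63 (4.08 to 9.01) and TOC1 at -2.64, and TRX3 was again without reads, at least 2609-fold lower. Of 14307 genes measured, 862 were at least 2-fold higher and 661 lower. The tasiRNA precursors were higher in 4 of 5 cases (median 1.28, or 1.29 at the floor) and the targets in 2 of 9 (0.78). Photosynthesis genes were higher in 15 of 25 cases (1.28), and abscisic acid genes were lower in 7 of 11 (-1.22). Salicylic acid genes were higher in 6 of 15 cases and lower in 2 (0.90, above all 10000 random lists), led by PR1 (3.41) and ICS1 (2.50), and jasmonate genes were lower in 6 of 10 (-1.17, below all 10000). The share of higher genes was 56.6%, and 76.5% with total nuclear counts, 69.0% with organelle reads in the total and 67.9% with the authors' ratios.

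Both rdr6-11 and the triple mutant were at least 2-fold higher than Col-0 for 510 of 13222 genes measured in both comparisons, and lower for 520. Independent lists would share 32.6 and 38.3, and simulated unchanged libraries shared 0.06 and 0. Across these genes r was 0.90 (simulated 0.53) with a covariance of 0.537 (simulated 0.0278). For the double and the triple mutant against Col-0, 178 of 13711 genes were higher in both and 146 lower, against 38.5 and 51.2 for independent lists and 0.05 and 0 in simulation. There r was 0.23 (simulated 0.55) with a covariance of 0.119 (simulated 0.0280). Both pairs share the Col-0 library, so its counting error enters both ratios. The simulated overlaps hold only for noise as small as that between the triple mutant and rdr6-11. Larger variation between libraries would raise them.

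In the rdr6-11 background, the loss of EIN5 and SKI2 came with few differences. The triple mutant against rdr6-11 compares libraries of the same clock state (morning minus evening median 0.60), and of 14234 genes 167 were at least 2-fold higher and 39 lower, 1.45% in all. With the counts of these libraries halved, as if each fragment had been counted by both of its reads, 89 were higher and 24 lower. The highest were 4 plant defensin genes, PDF1.2 (6.80, 6.08 to 7.77), PDF1.2c (5.53), PDF1.2b (5.13) and PDF1.3 (4.76), followed by the jasmonate-induced genes NATA1 (4.53) and JRG21 (3.96). The defensin ratios reflect few reads in rdr6-11: PDF1.2 had 13 there, against 1567 in Col-0 and 1832 in the triple mutant, with ratios to Col-0 of -7.33 and -0.53. NATA1 and JRG21, with at most 210 and 122 reads in either library, also had few reads in rdr6-11. JAZ7 (-2.13, -2.41 to -1.86), RRTF1 (-1.96) and PORA (-1.90), an enzyme of chlorophyll synthesis, were lowest.

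Heat shock genes were higher in 3 of 4 measured cases (median 1.25, above all 10000 random lists), HSP70 (1.75), HSP101 (1.27) and HSP90.1 (1.23), but the small heat shock proteins did not reach 100 reads. Part of this reflects lower heat shock values in rdr6-11. Against Col-0 the list median was -0.70 in rdr6-11 and 0.63 in the triple mutant, where 0 of 4 were at least 2-fold higher. Of 35 miRNA target genes 2 were higher, CSD1 (1.06) and CSD2 (1.02), copper/zinc superoxide dismutases, with a list median of 0.26 (percentile 99.98). Salicylic acid genes were higher in 3 of 14 cases (0.36, percentile 99.98), with PAD3 (1.67), PR1 (1.57) and PR2 (1.57). Anthocyanin genes had positive ratios in all 10 measured cases with 1 past 2-fold, UF3GT (1.32, list median 0.48). The jasmonate list had 3 of 10 genes higher, VSP1 (2.59), VSP2 (1.16) and LOX2 (1.02), and JAZ7 lower. PAD3, VSP1 and LOX2 were at least 2-fold lower in rdr6-11 than in Col-0, so their ratios here start from a low level. The tasiRNA precursors had a median of -0.07 and 0 at least 2-fold different. Higher genes made up 81.1%, but 92.0% with organelle reads in the total, 91.8% with the authors' ratios, 63.0% with a minimum of 20 reads and 37.1% with no minimum.

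Most of the genes different between the double mutant and Col-0 lay within 2-fold in the rdr6-11 background. Of the 2350 genes at least 2-fold different in the double mutant, 91.4% (90.2 to 92.5) lay within 2-fold in the triple mutant against rdr6-11, and a median of 16.5% of the log2 difference was kept. The interval treats genes as independent, which they are not. These values depended on the read minimum: with none, 64.0% lay within 2-fold, 7.03% was kept, and the share kept by higher genes turned from 22.6% to -11.5%. With organelle reads in the total, 24.3% was kept. Of all 14234 genes measured in the triple mutant against rdr6-11, only 1.45% were at least 2-fold different. The selected genes thus differed there more often than genes at large. Not all of them reached the 100 reads there that the 1.45% requires. Among those that did, 91.6% of the higher and 95.9% of the lower genes lay within 2-fold. Picking genes by a large ratio in 1 pair of libraries by itself lowers the share kept, and the size of this was not computed. Of the 1289 higher genes, 1140 lay within 2-fold, 123 were at least 2-fold higher as well and 26 were at least 2-fold lower (median log2 ratio 0.35). Of the 1061 lower genes, 1009 lay within 2-fold, 22 were also lower and 30 were higher (median -0.17, against -1.34 in the double mutant). With at least 100 reads in the triple mutant or rdr6-11, 737 of 805 higher genes lay within 2-fold, 65 were higher as well and 3 were lower. Of 1026 such lower genes, 984 lay within 2-fold, 18 were lower as well and 24 were higher. The single mutants, which have RDR6, also differed little from Col-0 in these genes, with medians of 0.42 (ein5-1) and 0.40 (ski2-3) for the higher genes and -0.28 in both for the lower genes. These medians share the Col-0 library with the choice of genes, which by itself moves them in the chosen direction. The triple mutant against rdr6-11 shares no library with it. The double mutant library thus stood apart from the single mutants as well. Across 15707 genes the log2 differences had an r of 0.26 (rho 0.38), or 0.14 with a minimum of 20 reads and 0.0063 with none.

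Genes that were higher in both backgrounds included HSP70, HSP101, HSP90.1, PR1 and PR2, and those lower in both included JAZ7 and RRTF1. For HSP90.1 the ratio to rdr6-11 starts from a lower level than in Col-0. PAP1 had 20 reads in rdr6-11 and 31 in the triple mutant, and HSP17.6A had 4 and 10, too few for the read minimum.

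**Figure D3:**
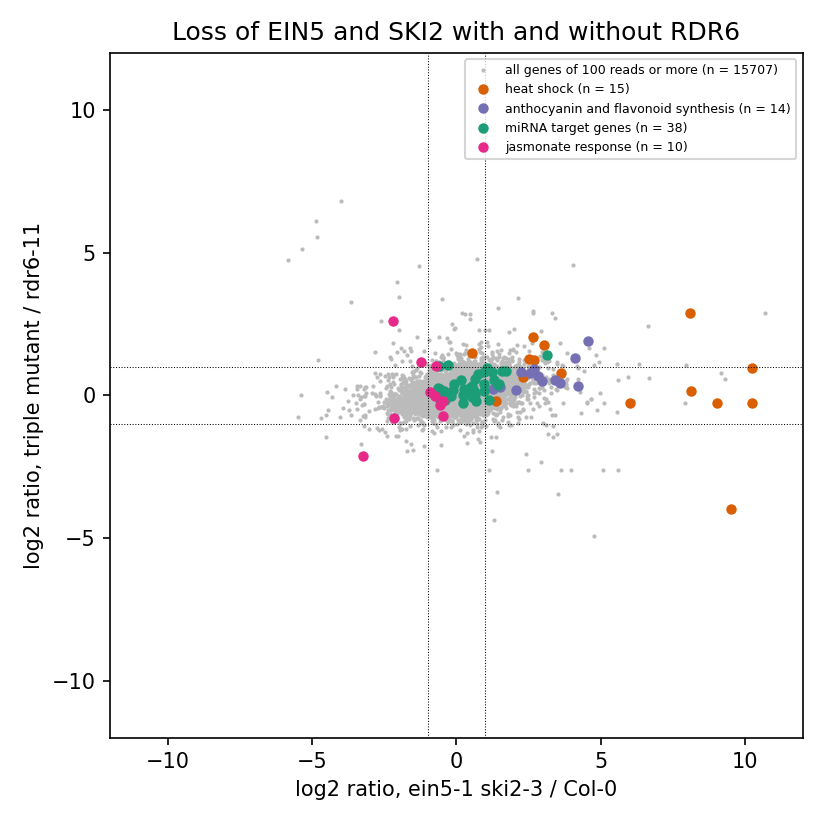
Log2 ratio of each gene for the loss of EIN5 and SKI2 with RDR6 (horizontal, double mutant against Col-0) and without RDR6 (vertical, triple mutant against rdr6-11), for genes with at least 100 reads in any of the 4 libraries; coloured points are list members and dotted lines mark 2-fold. The points spread more along the horizontal axis, and r was 0.26.

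The double mutant and the triple mutant differ by RDR6 and also by clock state. TRX3 (at least 2589-fold), LTP4, a lipid transfer protein (at least 621-fold), HSP22 (at least 205-fold), ATC, a relative of the flowering repressor TFL1 (at least 179.5-fold), and HSP21 (at least 146-fold) were higher in the double mutant, and the morning clock genes LHY (-7.08) and CCA1 (-5.79) were lower. Of 15642 genes measured, 1872 were at least 2-fold higher and 1740 lower, with a morning median of -5.06 and an evening median of 2.60. Of the higher genes, 477 were at least 2-fold different between rdr6-11 and Col-0, 472 of them in the opposite direction, and of the lower genes 462, with 445 in the opposite direction. Without genes different between rdr6-11 and Col-0, 1395 were higher and 1278 lower.

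Heat shock genes were higher in the double than in the triple mutant in 15 of 15 cases (median 4.29, or 4.31 at the floor), anthocyanin genes in 12 of 14 (2.57) and abscisic acid genes in 12 of 14 (2.09), all above the 10000 random lists. Only 4 heat shock and 10 anthocyanin genes were measured in the triple mutant against rdr6-11. The others passed the read minimum only through the double mutant, which favours a higher ratio. Silencing factors were higher in 6 of 19 cases (0.54, percentile 99.18), miRNA targets in 10 of 38 (0.32, percentile 96.67) and SMXL genes in 4 of 8 (1.03, percentile 99.92), with SMAX1 at 2.05. Photosynthesis genes were lower in 21 of 25 cases (-2.06, below all 10000), and tasiRNA precursors in 4 of 5 (-2.31, percentile 0.02). Abscisic acid, SMXL, photosynthesis and heat shock genes also differed between rdr6-11 and Col-0, in the opposite direction, the last with a median of -0.70 (percentile 1.71, 4 genes measured). The anthocyanin median there was -0.09. The 10 genes highest against both Col-0 and the triple mutant were HSP22, HSP21, NUDT24, LTP4, AT1G53540, HSP17.6A, HSP17.6II, HSP17.4, the sucrose transporter SWEET13 (5.96 against Col-0) and AT1G80130 (7.95). The share of higher genes was 51.8%, and 64.1% with total nuclear counts, 63.5% with organelle reads in the total, 63.8% with the authors' ratios and 65.5% with total nuclear counts without ribosomal RNA genes. With median-of-ratios size factors the majority turned, to 47.1% (1702 higher and 1908 lower).

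**Figure D4:**
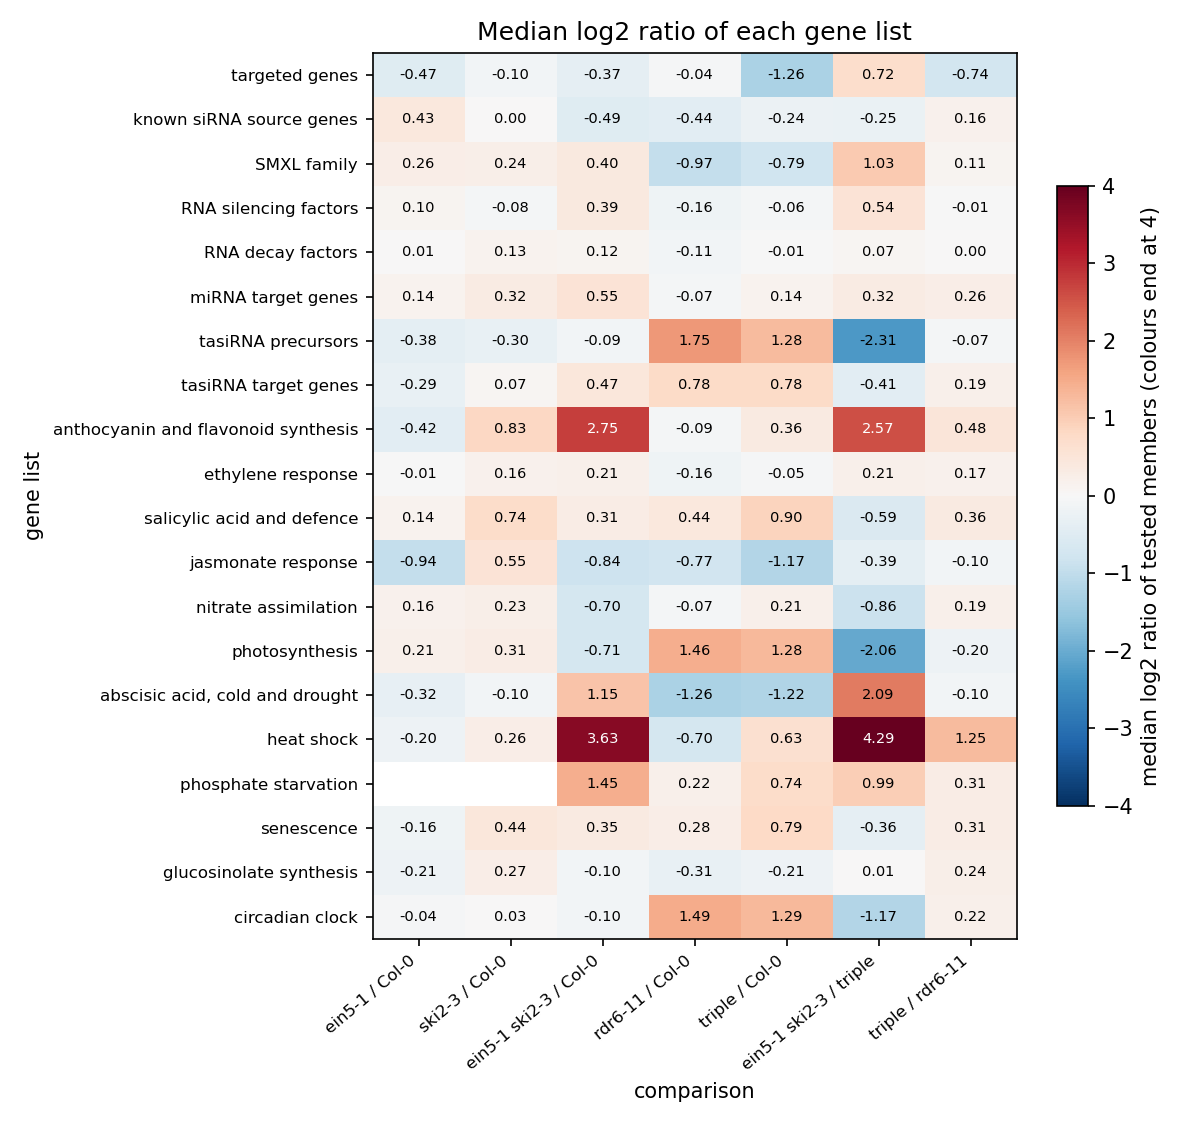
Median log2 ratio of the measured members of each gene list in each comparison, printed in each square; red is higher and blue is lower in the first genotype. Heat shock and anthocyanin lists are red in the double mutant against Col-0 (3.63 and 2.75) and against the triple mutant (4.29 and 2.57).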

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

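Of the tests in this part, those on paralogs, background reads, root tissue and floral tissue were written before their results were seen, and all others, with the summed reads of the floral and root markers and the median of all root markers, were chosen after the result was seen. In 56 genes the double mutant against Col-0 and the triple mutant against rdr6-11 were at least 2-fold different in opposite directions. Many of these rest on few reads: with at least 100 reads in the triple mutant or rdr6-11, 3 genes higher and 24 lower in the double mutant remained. Of these, near-identical plant defensin genes had the widest gaps: PDF1.2 stood at -3.99 and 6.80, PDF1.3 at -5.85 and 4.76, PDF1.2b at -5.37 and 5.13, and PDF1.2c at -4.85 and 5.53. The opposite signs of the defensin genes rest on the rdr6-11 library, which had 13, 10, 6 and 12 reads of them. Against Col-0 the triple mutant stood at -0.53, -1.44, -0.25 and -1.64. TPS04 stood at -4.79 and 1.24. Gaps of ELI3-2 (at most 41 reads in the rdr6-11 background) and HSP22 (at most 6) were as wide or wider but depended on the pseudocount. With 1 library per genotype these differences between backgrounds were not tested, and the defensin copies can share reads, so they count as fewer than 4 independent cases.

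Organelle genes, which no comparison used, were at least 2-fold above Col-0 in each mutant library: 1 gene in ein5-1, 13 in ski2-3, 10 in the double mutant, 42 in rdr6-11 and 24 in the triple mutant. At least 2-fold lower were 13 chloroplast and 4 mitochondrial genes in ein5-1, 10 and 5 in ski2-3, 33 and 6 in the double mutant, 8 and 7 in rdr6-11, and 8 and 7 in the triple mutant. These differences were not tested.

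The first pattern weighed was that the libraries with rdr6-11 stood apart. Counting both mates of a pair would make counts even without moving clock genes, since a factor common to all genes cancels in scaled ratios. The median absolute log2 ratio of the clock genes exceeded that of all measured genes by 3.67, so counting both mates cannot be the sole cause. Whether both mates were counted cannot be decided by this value. A harvest at another time of day fits the 7.85 between morning and evening genes. In 0 libraries did clock state and rdr6-11 genotype part, so an effect of RDR6 loss cannot be told from harvest time or batch.

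The second pattern was TRX3 without reads in both libraries with rdr6-11. A deletion or rearrangement at the locus fits on 1 side: the neighbouring gene UBC18 was at -3.19 in rdr6-11 and -2.06 in the triple mutant, but the other neighbour, COP8, was within 2-fold, at -0.18 and -0.41. Assignment of the reads to paralogs is excluded: the gain of the 4 paralogs was -4.39% of the reads lost. A time-of-day effect cannot be ruled out, although 0 other nuclear genes with at least 1000 reads in Col-0 had 2 or fewer in both libraries. Without sequence reads the locus could not be examined.

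The third pattern was the higher expression of heat shock and other stress genes in the double mutant. Background reads such as genomic DNA are excluded as the cause for the heat shock genes without reads in Col-0: they had a median 67.1 times the 99th percentile of pseudogenes without reads in Col-0. A larger share of floral tissue is excluded: the 7 floral markers had a median of -1.48, under the bound of 1 set beforehand, and though single markers had few reads, their sum had a log2 ratio of -1.13 (-1.74 to -0.53). Root tissue was not decided: the 3 of 11 root markers with at least 20 reads had a median of 1.07, all 11 had 0.44, and their sum had 0.80 (0.35 to 1.27), which spans the bound of 1. Growing or harvest conditions of that 1 library could give the same stress genes, and with 0 further libraries this cannot be told from an effect of genotype.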

How the results depend on the processing

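The alternatives named as added below were chosen after the data were seen. Each genotype had 1 library, and no paired analysis was run beyond setting the same loss side by side in different backgrounds. Of 182 counts under alternatives, 96 stayed within 1.5 times and 86 moved. Of 52 values on RDR6-dependence, 19 were the same, 32 moved and 1 reversed. Of 1106 list medians, 1042 were the same, 63 moved and 1 reversed: glucosinolate synthesis in ein5-1, to 0.062 with total nuclear counts. Of 14206 single-gene ratios, 11911 were the same and 2295 moved. Of those at least 2-fold in the analysis as reported, 0 of 4329 changed sign, and of the smaller ones 601 of 9877 did, SKI2 and RDR6 in the double mutant among them. In what follows, counts are genes higher and lower, and the correlation is that between the 2 backgrounds. Except for stricter rules or other read minimums, which alter the number of genes counted, the cause was not tested.

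With total nuclear counts there were 486 and 168 in ein5-1, 535 and 90 in ski2-3, 2978 and 442 in the double mutant, 945 higher in rdr6-11, 1351 and 414 in the triple mutant, and 18.7% was kept. With organelle reads in the total there were 356 higher in ein5-1, 2362 and 561 in the double mutant, 276 and 24 for the triple mutant against rdr6-11, and 1833 and 799 for non-additivity, with 24.3% kept and 89.7% within 2-fold. With the authors' ratios there were 335 higher in ein5-1, 201 in ski2-3, 2336 and 578 in the double mutant, 269 and 24 for the triple mutant against rdr6-11, and 1883 and 779 for non-additivity, with r at 0.23, 23.7% kept and 89.7% within 2-fold. With total nuclear counts without ribosomal RNA genes (added), there were 178 and 233 in ski2-3, and 2162 and 678 for non-additivity.

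With a minimum of 20 reads there were 406 and 574 in ein5-1, 607 and 402 in ski2-3, 2045 and 1597 in the double mutant, 1216 and 1314 in rdr6-11, 1455 and 1142 in the triple mutant, 501 and 294 for the triple mutant against rdr6-11, and 2213 higher for non-additivity, with r at 0.14, 14.0% kept and 86.0% within. With no minimum there were 2508 and 3151, 3248 and 2519, 5243 and 3464, 6379 and 2839, and 5099 and 3056 in the same 5 genotypes, 6332 and 4863 for the double against the triple mutant, 2573 and 4354 for the triple mutant against rdr6-11, and 7428 and 3866 for non-additivity, with r at 0.0063, 7.03% kept and 64.0% within. The median kept among higher genes reversed there, to -11.5%.

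With the whole interval beyond 2-fold there were 59 and 170 in ein5-1, 118 and 65 in ski2-3, 709 and 699 in the double mutant, 381 and 491 in rdr6-11, 511 and 438 in the triple mutant, 1231 higher for the double against the triple mutant, and 56 and 21 for the triple mutant against rdr6-11. At 4-fold there were 6 and 54, 16 and 23, 263 and 139, 126 and 183, 194 and 153, 465 and 387, and 20 and 1, in the same order. A pseudocount of 5 gave an r of 0.28 and 93.6% within. Halving the counts of the libraries with rdr6-11 (added) left 89 and 24 for the triple mutant against rdr6-11. Without genes 2-fold different between rdr6-11 and Col-0 (added), r was 0.34 and 92.9% lay within 2-fold.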

Other observations

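Nuclear ribosomal RNA genes held 2098477 reads in Col-0, 124308 in ein5-1, 36719 in ski2-3, 449838 in the double mutant, 207616 in rdr6-11 and 212483 in the triple mutant.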
